A study of Oryzias latipes with 16 samples.

How the data were processed

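The series holds 16 arrays, 1 per whole embryo. Per the labels, total RNA was prepared from individual stage 39 embryos of the HNI strain with a column kit that yields DNA and RNA together, checked by spectrophotometer and electrophoresis, labelled with Cy3 and hybridised to 1-colour Agilent arrays. Samples were grouped by the temperature and sex that the labels give, 4 embryos in each of 4 groups. The labels describe separate embryos, and do not say whether any of them were siblings.

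The main values are the processed signal intensity of each spot, which Agilent Feature Extraction 12.0.3.1 made within each array by background subtraction and detrending, with no scaling between arrays, per the file headers. The same deposited files hold flags of 0 or 1 per spot, set by Feature Extraction, for being well above background, saturated or an outlier. The deposited value table of the whole series holds the authors' processed values for 11668 entries, 11651 of them among the probes tested here. The authors' values in it are on a log2 scale, judged from the values: its 16 columns have medians of 8.58 to 8.59, so no probe was centred, and higher values are brighter. Its heat differences lie close to those after normexp subtraction and quantile normalization (r = 0.996 and slope 0.945 across probes, against r = 0.913 and slope 0.568 for the processed signal). Each of its 16 columns lay closest to the scanner file of its own array. How its entries were chosen and which steps made it are not given in the sources used here, so it served only as an alternative.

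From these files, control spots and outlier spots (117 to 180 of 43803 spots per array) were left out, spots of 1 probe were averaged, log2 was taken and the 75th percentile of each array was subtracted. A probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 18170 of 22773 probes. Each probe was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes and 4 group means over all 16 arrays, so that the groups share 1 estimate of the spread (12 residual and 2.69 prior degrees of freedom). Tests were 2-sided, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. The contrasts were heated minus control in females, in males and over both sexes, the difference of these responses, and male minus female at each temperature. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

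Where a probe was not well above background on any of the arrays on 1 side of a contrast (4 in 1 sex, 8 over both), a fold is given as a lower bound. For this, the mean of the brighter group was set against the mean, over the dim group's arrays, of the higher of the probe's own signal and the lowest signal among probes well above background on that array. Over both sexes lipc, med27, slc2a11, ifih1, rag2, hgd, tdrd7, slc13a1, aanat2, AB568293 and XM_004069372 were above background on 1 to 4 of the 8 arrays of 1 side, so their fitted differences there partly rest on background. Array values carry no counts, so signal over background and the number of arrays set the precision.

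Probe names came from the scanner files' accessions and descriptions, updated through a RefSeq table of the assembly ASM223467v1. Of 22773 probes 9826 matched by accession, 10076 by gene number and 31 by symbol, 529 were named from their GenBank description and 2311 did not match. A symbol was found for 10928 probes of 9896 genes, and 9534 probes matched a gene without a symbol. The build behind the array's design is not given in the sources used here, so no coordinates are printed. A gene with several probes was represented by the probe with the highest mean. Of the named genes 20 had more than 1 tested probe, 0 of them with calls in opposite directions and 4 with probes of different sign.

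Gene lists of pathways, organs and cell types were written from textbook knowledge, and 40 of the 43 had the 5 measured members needed for a test. They were tested over 8473 genes with a symbol by camera with an inter-gene correlation of 0.01, beside camera with an estimated correlation, and adjusted over the lists. A camera test compares a list's members with all other genes. Counts of members past the threshold are over all probes, and counts adjusted over the list alone are given beside them.

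The genes named in the text follow a rule. For each temperature contrast it takes, among called probes with a symbol whose compared groups do not overlap on any array (in neither sex for the contrast over both), the 10 with the largest positive and the 10 with the largest negative difference, 1 probe per gene. For the difference of the responses and the 2 sex contrasts it takes the 5 probes with a symbol and the smallest p. In each list it takes up to 4 members with the smallest p over both sexes. Sex marker genes are named whatever their values, and were tested by exact permutation of the sex labels within each temperature. Genes named outside this rule are said to be so where they appear, apart from the list members nrgn, srebf2, a1cf and c9, which were chosen after their values were seen.

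The groups, contrasts, filter, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives were quantile or median scaling, normexp background subtraction with an offset of 50, 2 other filters on dim probes, the authors' table, slide as a fixed or random block, the replicate number as a block, fits of the compared groups alone, an intensity trend, array weights, a 2-fold minimum, the mean of a gene's probes and leaving out each array in turn. Scan day as a block, leaving out slide 3, temperature alone without sex, and normexp with quantile normalization were added after seeing the data. Slides were read from the scanner files: 6 slides hold 2 or 3 arrays each, every slide holds both temperatures and no slide holds all 4 groups. Control females were all at position 1 of their slide, heated females at 2, heated males at 3 and control males at 1 or 2. On every slide the heated arrays thus lay at a later position than the control arrays. Comparisons within slides and slide blocks do not separate temperature from position, which was not tested. The arrays were scanned on 2 days.

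The fit was tested on simulated data built from these arrays' means and spreads over 18155 probes, 200 of them changed. For females it recovered 17.9%, 62.7% and 86.4% of probes changed by 0.5, 1 and 2 on the log2 scale, with 5.93% of calls false. For males these were 4.48%, 44.8% and 81.8% (4.40% false), and over both sexes 28.4%, 85.1% and 90.9% (4.90% false). For the difference of the responses they were 2.99%, 28.4% and 69.7% (5.63% false). Each rate rests on 1 random draw with 66 or 67 probes per size. The female and male contrasts have equal group sizes and share 1 spread, so their rates differ by the draw alone. The rates hold for 200 changed probes and need not hold for the temperature contrasts, where more probes were called. Among 40 simulated lists all 5 that were shifted were called and 0 others. The simulated probes varied independently of each other, so this does not show how often lists of correlated genes are called by chance. In the real arrays, reassigned temperature labels gave a median of 8 called lists.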

Results

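Gene expression was measured in single whole embryos of the Japanese medaka (Oryzias latipes), a small freshwater fish with an XY system of sex determination, of the inbred HNI strain. The embryos were collected at stage 39, the stage at which medaka hatch. They were kept at 24 °C as controls or at 32 °C from the first day after fertilization, and each was labelled female or male. This gave 4 groups of 4 embryos, and the RNA of each embryo was hybridised to an array of its own, so that n counts embryos. The design asks how a raised incubation temperature changes transcript levels in embryos of each labelled sex and whether the sexes respond differently.

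The 16 arrays were 1-colour expression arrays with 22773 probes, of which 18170 entered the tests. Values are log2 signals relative to the 75th percentile of their array, and differences are heated minus control with their standard error (SE). The median processed signal of an array ranged from 34.0 to 64.4 intensity units, the 75th percentile from 181 to 336, and 0 probes were saturated. Between 70.2% and 85.1% of probes per array were well above background, with means of 77.3% in heated and 76.4% in control embryos (2-sided exact permutation test, p = 0.634, n = 8 and 8). The precision of all values is limited by the number of arrays.

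The first principal component held 32.6% of the variance and separated the temperatures without overlap, with heated embryos between 28.96 and 47.49 and controls between -70.14 and -4.20. Control female 4 at -4.20 and control male 4 at -15.00 lay nearest to the heated embryos. The second component held 10.4% and placed control female 3 (-50.86) and heated female 1 (-54.70), both on slide 3, apart from the rest.

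**Figure D1:**
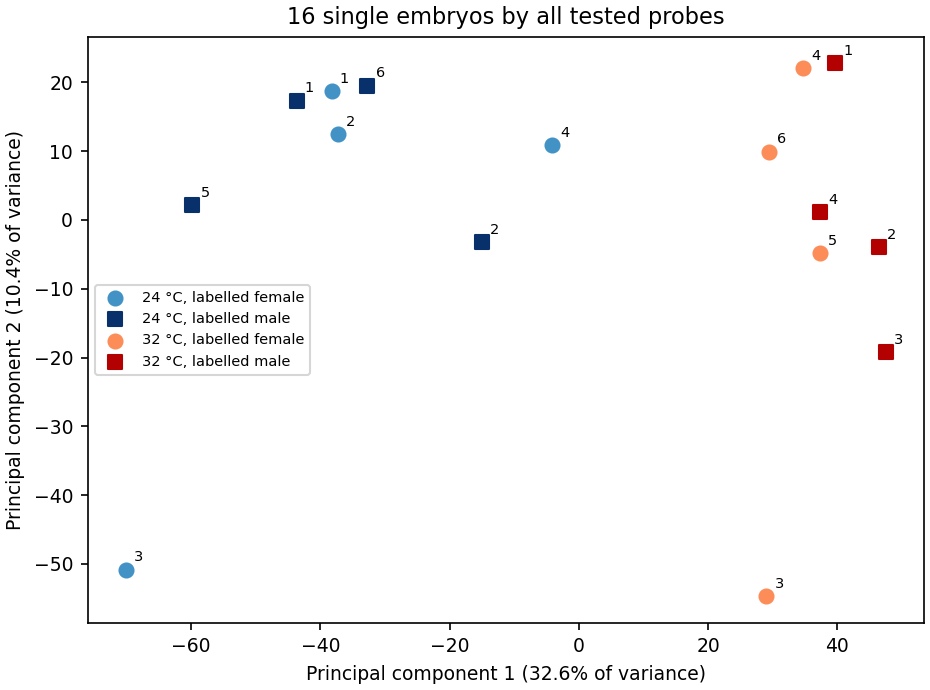
Scores of the 16 embryos on the first 2 principal components of the log2 signals of the tested probes (axes in score units, with the percent of variance), coloured by group, with the number of the slide beside each point. Heated embryos lie above 28 and control embryos below -4 on the first component.

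Across both labelled sexes, the largest falls among probes with a gene symbol were those of the hatching enzymes, the proteases that dissolve the egg envelope. The low choriolytic enzyme lce, which was well above background in 8 of 8 control embryos and 0 of 8 heated embryos, was at least 448-fold lower at 32 °C (fitted log2 difference -9.44 ± 0.71, adjusted p = 1.45e-06). The hatching enzyme-like protease mahce was at least 1278-fold lower, with the same 8 of 8 and 0 of 8 embryos above background (-10.76 ± 0.72, adjusted p = 5.92e-07). The high choriolytic enzyme probes hce (-7.77 ± 0.79) and hceb (-7.63 ± 0.77) also fell and stayed above background in every embryo (adjusted p = 2.55e-05 for each). In control female 4 the hce signal was -0.06, against 5.51 to 6.66 in the other control females, and without this embryo the differences of mahce, lce, hce and hceb were -11.44, -10.12, -8.52 and -8.37. Within each of the 6 slides the mean signal of 5 hatching enzyme probes was lower in heated embryos, by between -4.58 and -11.01 on the log2 scale.

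Other transcripts that fell in both sexes without overlap between temperatures included tmprss9, a transmembrane serine protease, at -5.46 ± 0.58 (adjusted p = 4.31e-05). The nuclear receptor coactivator ncoa3 (-2.27 ± 0.24) and the putative amino acid transporter slc38a11 (-2.02 ± 0.25) fell. So did pkig, an inhibitor of cAMP-dependent protein kinase (-1.92 ± 0.15, adjusted p = 1.64e-06), and dhrs7c, a dehydrogenase of striated muscle (-1.71 ± 0.23). The endosomal syntaxin stx12 fell by 1.88 ± 0.63 (adjusted p = 0.0373), a call that ended without any 1 of the 8 control embryos (adjusted p up to 0.0588). Its signal was -6.90 in heated female 1 and -7.24 in heated male 2, against -3.66 to -3.0 in the other 6 heated embryos, and its difference was -1.40 without the first and -1.38 without the second.

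Among transcripts that rose, hepatic lipase lipc, which clears lipoprotein lipids from the blood, was 35.3-fold higher at 32 °C (fitted log2 difference 5.14 ± 0.47, adjusted p = 1.14e-05). It was above background in 3 of 8 control and 8 of 8 heated embryos. The ammonia channel rh50 rose by 3.63 ± 0.77 (adjusted p = 0.00397, 3.03 without control female 3) and the embryonic globin gb by 2.59 ± 0.30 (adjusted p = 7.85e-05), and 3 of the 7 gb probes passed the test, all of them higher. Deiodinase dio2, which activates thyroid hormone, was at least 3.75-fold higher (fitted 2.39 ± 0.26, adjusted p = 4.66e-05), with 0 of 8 control and 8 of 8 heated embryos above background. The myosin heavy chain mmyhc3 was at least 3.27-fold higher (2.60 ± 0.17, adjusted p = 4.37e-07), above background in 0 of 8 control and 6 of 8 heated embryos. The ribosomal protein rpl15 rose by 2.72 ± 0.17 and the Mediator subunit med27 by 2.5 ± 0.11. The phospho-lyase etnppl, the hexose transporter slc2a11 and lanosterol synthase lss, an enzyme of cholesterol synthesis, rose by 2.41 ± 0.34, 2.39 ± 0.45 and 2.38 ± 0.37 (adjusted p = 0.000345, 0.00185 and 0.000616).

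In this comparison of 8 heated with 8 control embryos, limma called 5045 of 18170 probes (27.8%) at an adjusted p under 0.05, 1834 higher and 3211 lower at 32 °C, from 4735 distinct genes. Of these, 829 differed at least 2-fold, 560 higher and 269 lower. The temperatures did not overlap on any array of either sex for 1182 of the called probes, and over all probes the share was 6.52%, where chance gives 0.0408%. Slide as a block left 3871 calls. The share of called probes that were higher was 36.4% with 75th percentile scaling and 49.98% with median scaling, since the median difference of all tested probes was -0.09 under the first.

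Background subtraction by normexp followed by 75th percentile scaling, which shifted the median log2 difference of all probes to 0.22 in females and -0.25 in males, left 408 calls in this comparison. Quantile normalization after the same subtraction, an alternative chosen after seeing the data, gave 4732.

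**Figure D2:**
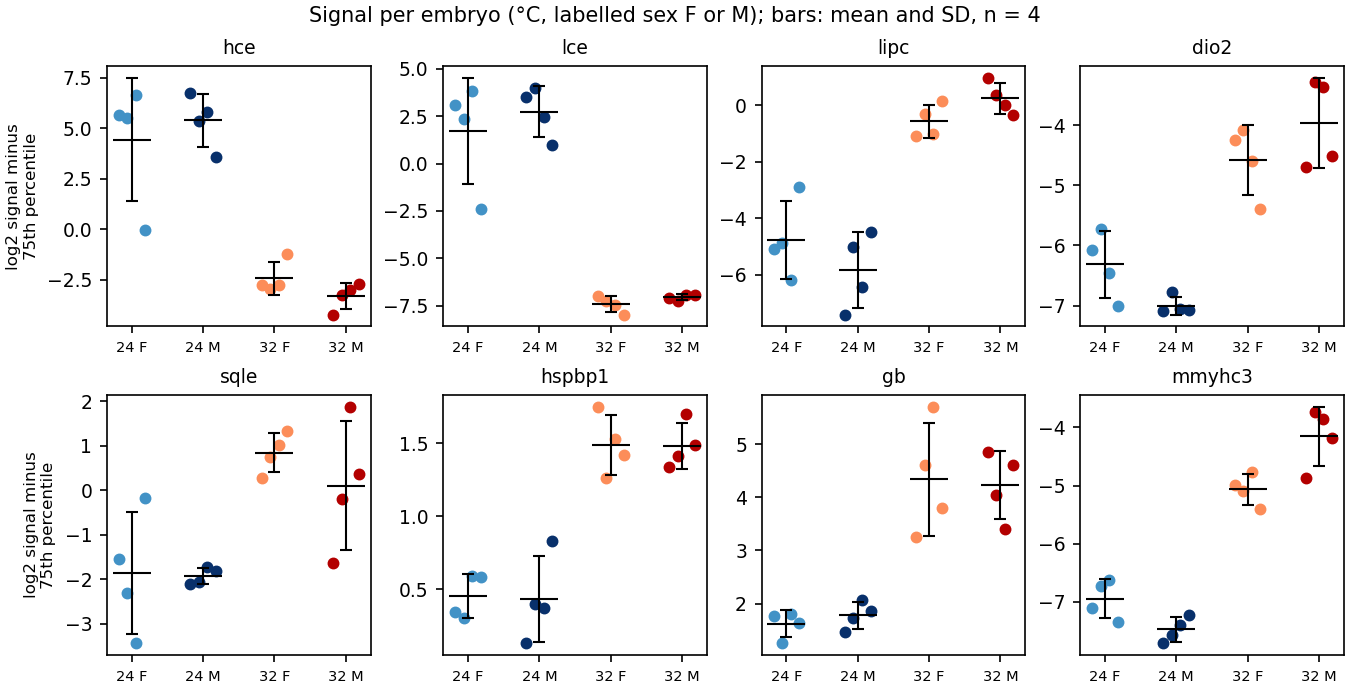
Log2 signal relative to the array's 75th percentile (vertical axis) of 8 genes in the 4 groups, with 1 point per embryo and bars for the mean and SD (n = 4 per group). lce and hce lie lower, and lipc, dio2, sqle, hspbp1, gb and mmyhc3 higher, at 32 °C than at 24 °C.

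Enzymes of cholesterol synthesis formed the gene list with the smallest camera p in the comparison over both sexes. Of its 20 measured members 14 rose, 1 fell and 5 did not pass the test (15 and 1 adjusted over the list alone), with a median log2 difference of 0.98. The delta-reductase dhcr7 rose by 0.98 ± 0.14, the sterol isomerase ebp by 1.81 ± 0.26, lss by 2.38 ± 0.37 and the desaturase sc5d by 1.61 ± 0.27, while srebf2, the transcription factor that drives the pathway, fell by 0.44 ± 0.15. The list's adjusted p was 1.79e-08 with the preset correlation, and adjusted p = 0.0619 with an estimated correlation. Blocking on slide gave a median of 0.91, and the medians within the 6 slides lay between 0.44 and 1.46.

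Part of the immune genes rose in 2 of the fixed lists. Among leukocyte markers 6 of 12 rose and 0 fell (7 and 0 adjusted over the list alone), including the lymphoid factor ikzf1 (0.69 ± 0.10), the T cell kinase lck (1.09 ± 0.17), lysozyme lyz (2.13 ± 0.39) and the recombinase rag2 (1.1 ± 0.24). Their median was 0.47 (adjusted p = 1.09e-05, and adjusted p = 0.0619 with an estimated correlation), 0.56 with slide as a block and 0.52 to 0.91 within slides. Of 16 inflammation and interferon genes 7 rose and 0 fell (8 and 0 over the list alone). They included the immunoproteasome subunits psmb9 (1.88 ± 0.22) and psmb8 (1.70 ± 0.32), the viral RNA sensor ifih1 (1.14 ± 0.20) and the receptor tlr3 (0.51 ± 0.09). Their median was 0.40 (adjusted p = 2.60e-04, and adjusted p = 0.214 with an estimated correlation), 0.43 with the slide block and -0.02 to 0.60 within slides, above 0 on 5 of 6.

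Part of the genes of digestive organs and of lipid and foreign compound metabolism rose in 4 lists. In the liver list 5 of 18 members rose and 0 fell, the same over the list alone, among them the clotting inhibitor serpinc1 (1.05 ± 0.15), cyp3a (2.42 ± 0.40), the tyrosine-degrading hgd (3.74 ± 0.75) and the plasmin inhibitor serpinf2 (0.51 ± 0.11). The liver median was 0.49 (adjusted p = 2.54e-05, and adjusted p = 0.220 with an estimated correlation), 0.50 with the slide block and 0.07 to 0.78 within slides. In exocrine pancreas and intestine 4 of 8 rose and 0 fell (5 and 0 over the list alone), with the intestinal fatty acid carrier fabp2 at 1.33 ± 0.22, the digestive phospholipase pla2g1b at 2.22 ± 0.51, lactase lct at 1.59 ± 0.44 and the meprin mep1b at 0.91 ± 0.28. The mep1b call ended without control male 1, heated female 3 or heated male 2 (adjusted p up to 0.0570). That list's median was 1.12 (adjusted p = 0.00188, and adjusted p = 0.636 with an estimated correlation), 1.24 with the slide block and 0.43 to 1.59 within slides.

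Of 25 genes of fatty acid oxidation and PPAR-alpha targets 7 rose and 0 fell, the same over the list alone, including the lipid droplet protein plin2 (1.52 ± 0.30), the peroxisomal enzyme ehhadh (0.89 ± 0.18) and the mitochondrial cpt2 (0.55 ± 0.16). The median was 0.22 (adjusted p = 6.25e-04, and adjusted p = 0.602 with an estimated correlation), 0.21 with the slide block and -0.12 to 0.54 within slides. Among 16 antioxidant and xenobiotic genes 6 rose and 1 fell (7 and 1 over the list alone). The monooxygenase cyp1a rose by 2.1 ± 0.39, the drug efflux pump abcb1 by 1.71 ± 0.45 and the peroxidase gpx1 by 0.41 ± 0.12, and the peroxiredoxin prdx5 fell by 0.50 ± 0.10. This list's median was 0.27 (adjusted p = 0.00967, and adjusted p = 0.220 with an estimated correlation), 0.28 with the slide block and -0.10 to 0.35 within slides.

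Most of the measured neuronal genes and a smaller part of the skeletal genes fell. Of 25 neuronal genes 18 fell, 1 rose and 6 did not pass the test (19 and 1 over the list alone), and the one that rose was nrgn (0.63 ± 0.17). The tubulin regulator stmn4 (-0.62 ± 0.12) and the synaptic proteins cplx2 (-0.71 ± 0.15) and syn2 (-1.01 ± 0.22) were lower. The neuronal median was -0.49 (adjusted p = 2.56e-05, and adjusted p = 0.602 with an estimated correlation), -0.45 with the slide block and -0.83 to 0.03 within slides, below 0 on 5 of 6. In cartilage and bone 7 of 27 fell and 0 rose, the same over the list alone, including the chondrocyte factors sox6b (-0.81 ± 0.11) and sox5 (-0.94 ± 0.16) and the matrix genes matn3 (-1.50 ± 0.24) and col9a1 (-0.85 ± 0.14). The median was -0.29 (adjusted p = 0.0133, and adjusted p = 0.649 with an estimated correlation), -0.30 with the slide block and -0.48 to -0.21 within slides. The cartilage and bone call ended without control female 2 (adjusted p = 0.0687).

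Cell cycle genes ranked higher as a list, with a median of 0.38 over 45 members (adjusted p = 1.09e-06, and adjusted p = 0.649 with an estimated correlation), while few passed the test singly. The replication genes pola1 (0.43 ± 0.14), rfc5 (0.56 ± 0.19) and gins1 (0.60 ± 0.21) were among the 4 that rose, and the 1 that fell was the cyclin ccnd1 (-0.37 ± 0.11), with 0 in each direction over the list alone. The list's median was 0.25 under the slide block and 0.02 to 0.70 within slides. Leaving out single arrays ended the calls of pola1 for 7 arrays and of rfc5 and gins1 for 11 each.

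Of 22 heat shock proteins and cytosolic chaperones 3 rose and 0 fell, the same over the list alone: the Hsp70 nucleotide exchange factor hspbp1 (1.04 ± 0.11, adjusted p = 4.19e-05) and the Hsp90 cochaperones fkbp4 (0.61 ± 0.10) and chordc1 (0.61 ± 0.13). These 22 are the measured members of 42 listed symbols, so the list does not cover every chaperone probe on the array. An Hsp90-alpha-like transcript without a symbol (XM_004083771), named after its value was seen, lay outside the list. In females it rose by 2.76 ± 0.24 (limma adjusted p = 5.16e-05). The list's median was 0.00 and its mean 0.20 (camera adjusted p = 0.0315, and adjusted p = 0.602 with an estimated correlation), with a median of -0.02 under the slide block and -0.10 to 0.52 within slides. The call of this list ended without control female 3, heated female 1 or heated male 3 (adjusted p up to 0.0961). It also ended with quantile normalization, with normexp, with slide as a block (adjusted p = 0.0546) and without slide 3, an alternative chosen after seeing the data, while 5 of 9 such settings kept it (adjusted p from 0.0316 to 0.305 over the 9).

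The 11 lists above were those called among the 40 tested, and none of the 11 was called with an estimated correlation. The other 29 had adjusted p between 0.0731 and 0.998.

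**Figure D3:**
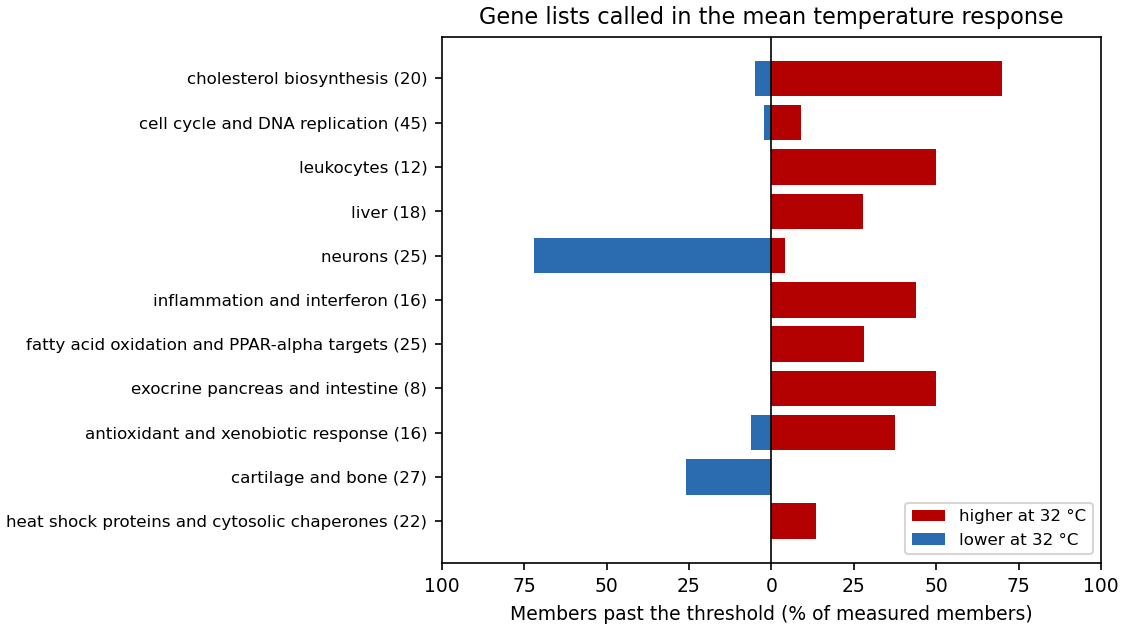
Percent of the measured members of each of the 11 called gene lists whose probe was higher or lower at 32 °C past the threshold, over both sexes (horizontal axis in percent, 1 pair of bars per list). In the cholesterol synthesis list 14 of 20 members were higher, and in the neuronal list 18 of 25 were lower.

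In embryos labelled female, heat raised lipc by 4.21 ± 0.67 (adjusted p = 0.00337, n = 4 and 4 embryos in a limma fit over all 16), med27 by 2.70 ± 0.16 (at least 6.48-fold) and rpl15 by 2.61 ± 0.25. Squalene monooxygenase sqle, a rate-limiting step of cholesterol synthesis, rose by 2.70 ± 0.66 and lss by 2.31 ± 0.52. The inducible chaperone hsp70-5 was at least 2.66-fold higher (fitted 2.43 ± 0.35, adjusted p = 0.00201), with 0 of 4 control and 4 of 4 heated females above background. The chemokine cxcl13 rose by 2.15 ± 0.44, psmb9 by 2.12 ± 0.31, slc2a11 by 2.64 ± 0.63 and the mitochondrial GTPase noa1 by 2.1 ± 0.23 (at least 3.41-fold). lipc, cxcl13 and slc2a11 were above background in 1 of 4 control females each, so their differences rest partly on background.

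Among probes with a gene symbol, the largest falls in females were those of mahce (at least 716-fold lower, fitted -10.09 ± 1.02) and lce (at least 271-fold lower, -9.12 ± 1.0). hce (-6.86 ± 1.11), hceb (-6.70 ± 1.1), tmprss9 (-4.64 ± 0.82) and ncoa3 (-2.37 ± 0.35) fell as well. So did slc38a11 (-2.02 ± 0.35), pkig (-1.59 ± 0.21) and dhrs7c (-1.56 ± 0.33). Without control female 4 the fitted differences of mahce, lce, hce, hceb and tmprss9 were -11.45, -10.49, -8.36, -8.16 and -5.67, and those of lipc and slc2a11 were 4.83 and 3.34. Without control female 3 mahce, lce, hce and hceb were at -9.38, -8.42, -6.12 and -5.98, and without control female 1 tmprss9 was at -4.03. The chaperone subunit pfdn6 fell by 2.18 ± 0.56 on 1 of its 2 probes (adjusted p = 0.0349), with 1 of 4 heated females above background, and over both sexes its probes gave -2.14 and 0.26. Leaving out single arrays ended the calls of sqle (6 arrays, adjusted p up to 0.0780), slc2a11 (4, up to 0.0767), lss (4, up to 0.0638), pfdn6 (7, up to 0.0833) and dhrs7c (without control female 2, 0.0544).

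Among the lists, 8 were called in females, and none of the 8 with an estimated correlation (lowest adjusted p 0.186). Cholesterol synthesis (6 of 20 rose, median 0.83), leukocytes (2 of 12 rose, 0.47), inflammation and interferon (2 of 16 rose, 0.30) and fatty acid oxidation (1 of 25 rose, 0.18) ranked higher, as did cell cycle (0 of 45 rose and 1 fell, 0.48). Neurons (8 of 25 fell, -0.57), cartilage and bone (3 of 27 fell, -0.27) and glycolysis and gluconeogenesis (2 of 14 fell, -0.39) ranked lower.

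limma called 1257 probes in females, 536 higher and 721 lower at 32 °C, 417 of them at least 2-fold, and 54.9% of calls were higher with median scaling against 42.6% here. The temperatures did not overlap for 1105 of the called probes. Over all tested probes they did not overlap for 2252 (12.4%), where chance gives 2.86%. On slides 3 and 4, the 2 that hold both temperatures in females, 99.9% and 98.6% of called probes went the same way, and 90.1% and 85.3% of those called without that slide did. The count was 308 with slide as a block, 14 with normexp and 75th percentile scaling, 169 in a fit of the female arrays alone and 373 without slide 3, an alternative chosen after seeing the data. It was 2263 without control female 4, and without control female 1, 2 or 3 or heated female 2, 3 or 4 it was 584, 422, 549, 593, 831 or 735.

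In embryos labelled male, lipc rose by 6.08 ± 0.67 (adjusted p = 0.000163, n = 4 and 4 embryos), above background in 2 of 4 control and 4 of 4 heated males. mmyhc3 was at least 6.58-fold higher (fitted 3.32 ± 0.24) and dio2 at least 6.2-fold higher (3.04 ± 0.36), each above background in 0 of 4 control and 4 of 4 heated males. The detoxifying cytochromes cyp2p3 and cyp1a rose by 4.04 ± 0.89 and 3.03 ± 0.55, lysozyme lyz by 2.90 ± 0.55 and rh50 by 3.82 ± 1.09. The astacin protease mc6ast3, guanine deaminase gda and pla2g1b rose by 3.30 ± 0.77, 2.95 ± 0.83 and 2.87 ± 0.72.

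Heat lowered mahce in males by at least 2282-fold (fitted -11.43 ± 1.02) and lce by at least 741-fold (-9.76 ± 1.0). hce (-8.67 ± 1.11), hceb (-8.57 ± 1.1) and tmprss9 (-6.29 ± 0.82) fell as well. The Mediator subunit med20 (-2.72 ± 0.70), pkig (-2.25 ± 0.21) and ncoa3 (-2.16 ± 0.35) fell. zar1, a gene of the oocyte and early embryo, fell by 2.08 ± 0.36, and slc38a11 was lower too (-2.01 ± 0.35). Of the 4 heated males, zar1 was above background in 1 and tmprss9 and med20 in 2, and cyp2p3 was in 2 of 4 control males. Leaving out single arrays ended the calls of rh50 (7 arrays, adjusted p up to 0.125), gda (6, up to 0.113), med20 (7, up to 0.0861) and pla2g1b (5, up to 0.0767), and leaving out control male 1 those of cyp2p3 (0.0529) and mc6ast3 (0.0594). The differences of lce, hce and rh50 were -10.35, -9.27 and 4.55 without control male 4, those of med20 and cyp2p3 -3.5 and 4.63 without control male 2, and that of rh50 was 3.14 without control male 3.

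In males 12 lists were called. Cholesterol synthesis (7 of 20 rose, median 0.90) and leukocytes (5 of 12 rose, 0.61) were also called with an estimated correlation (adjusted p = 0.0473 for each). The other 10 were not (adjusted p from 0.0686 to 0.735). Liver (7 of 18 rose, 0.81), inflammation and interferon (5 of 16 rose, 0.36), exocrine pancreas and intestine (2 of 8 rose, 1.21) and fatty acid oxidation (1 of 25 rose, 0.23) ranked higher. Antioxidant genes (2 of 16 rose and 1 fell, 0.24), chaperones (3 of 22 rose, 0.06) and cell cycle genes (0 of 45, 0.29) did too. The ribosomal proteins (6 of 50 rose) had a median of -0.00 under an upward camera test. Neurons (2 of 25 fell, -0.42) and cartilage and bone (5 of 27 fell, -0.33) ranked lower.

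In males 1868 probes were called, 801 higher and 1067 lower, 754 of them at least 2-fold, and 62.9% of calls were higher with median scaling against 42.9% here. The temperatures did not overlap for 1708 called probes. Over all tested probes they did not overlap for 3822 (21.0%), where chance gives 2.86%. On slides 1 and 2, the 2 that hold both temperatures in males, 99.7% and 97.5% of called probes went the same way, and 97.0% and 81.7% of those called without that slide did. The count was 487 with slide as a block, 107 with normexp and 75th percentile scaling, 4593 with array weights and 682 with scan day as a block, the last chosen after seeing the data. Higher and lower calls numbered 365 and 122 with the slide block, 90 and 17 with normexp and 420 and 262 with scan day. With array weights they were 1581 and 3012, and with a 2-fold minimum 475 and 279. Without control male 1, 2 or 3 or heated male 1, 3 or 4 it was 663, 1107, 831, 1044, 1086 or 1143.

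Most called probes moved the same way in the labelled sexes. lipc, med27, rpl15, mahce, lce, hce, hceb, tmprss9, ncoa3, pkig and slc38a11 passed the test in each sex with the same sign. In all, 351 probes rose in both sexes, where 23.6 would if the calls were independent, and 408 fell in both, where 42.3 would. None (0) was called in opposite directions. Of the 2366 probes called in either sex, 97.9% had the same sign in both. Across the 18170 probes the log2 differences of the sexes had a Pearson r of 0.756 and a Spearman rho of 0.711, a relation across probes, which are not independent replicates. That r was 0.263 with normexp and 75th percentile scaling, 0.643 with slide as a block, 0.635 with scan day as a block and 0.662 without slide 3, the last 2 chosen after seeing the data. The sexes share no control embryo, but their contrasts use the same estimate of a probe's spread, so their calls are not independent. The numbers given for independent calls are therefore not what chance alone would give.

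The 759 probes called alike in both sexes became 132 with slide as a block, 12 with normexp and 75th percentile scaling, and, as alternatives chosen after seeing the data, 275 with scan day as a block and 286 without slide 3. Without 1 array the count was lowest without control female 2 (334) and highest without control female 4 (1138). It was 414 and 429 without control female 1 and 3, 381, 478 and 407 without control male 1, 2 and 3, 427 and 488 without heated female 2 and 4, and 504, 498 and 487 without heated male 1, 3 and 4.

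**Figure D4:**
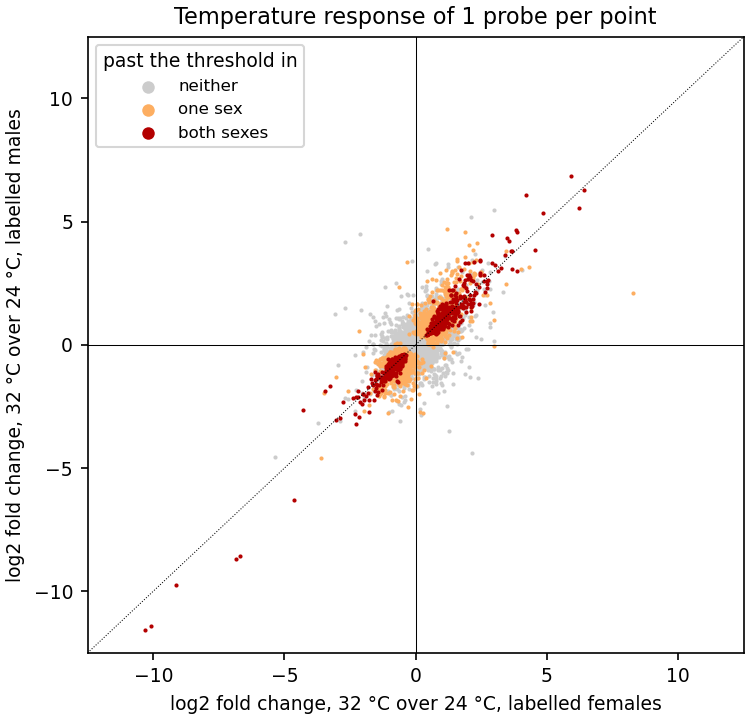
Log2 difference between 32 °C and 24 °C in embryos labelled female (horizontal axis) against that in embryos labelled male (vertical axis), 1 point per tested probe, coloured by whether it passed the test in neither, one or both sexes. The 759 probes called alike in both sexes lie in the quadrants where both differences have the same sign.

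No single probe passed the test of the difference between the male and the female response (0 of 18170 by limma, smallest adjusted p 0.70). An unadjusted p under 0.05 was reached by 446 probes, where 908.5 are expected by chance. The 5 symbol-bearing probes with the smallest p were the collagen glycosyltransferase-like cercam (-1.41 ± 0.26), the anticoagulant protease proc (1.12 ± 0.26), mmyhc3 (1.44 ± 0.34), proser2 (-1.63 ± 0.40) and the tubulin nucleation gene tubgcp3 (-0.88 ± 0.22), none past the threshold.

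As lists, 3 of 40 were called in this difference. The liver list ranked higher in males (median of the male minus female differences 0.58, adjusted p = 2.73e-09, and adjusted p = 0.182 with an estimated correlation). a1cf, a cofactor of RNA editing in liver, had a difference of -0.01 in females and 1.40 in males, and the complement gene c9 -0.01 and 0.87, while hgd had 4.32 and 3.17. 0 of the 18 liver members passed the test of the difference singly. Ribosomal protein genes had a median of 0.15 (adjusted p = 3.16e-06, and adjusted p = 0.803 with an estimated correlation) and photoreceptor and retina genes -0.29 (adjusted p = 0.0268, and adjusted p = 0.803 with an estimated correlation). The photoreceptor call ended with slide as a block (adjusted p = 0.393), with scan day as a block (0.437), with normexp and without slide 3, and 5 of 9 such settings kept it (adjusted p from 0.00817 to 0.681 over the 9). It ended without any 1 of 10 arrays (up to 0.220). Scan day 2 held only control males and heated females, so that it is aligned with this difference.

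Between embryos labelled male and female, 0 probes passed the test at 24 °C (limma, smallest adjusted p 0.870) and 0 at 32 °C (0.166). Unadjusted p under 0.05 was found for 558 and 483 probes, where 908.5 are expected by chance. At 24 °C the 5 symbol-bearing probes with the smallest p were proser2 (male minus female 1.37 ± 0.28), the kinase inhibitor mbip (0.56 ± 0.13), the biotin ligase hlcs (0.74 ± 0.19), the nuclear membrane protein lemd3 (0.51 ± 0.13) and the methyltransferase hemk1 (-1.16 ± 0.30). At 32 °C they were cercam (-1.09 ± 0.19, adjusted p = 0.208), proc (0.89 ± 0.18), the corepressor rcor3 (-2.34 ± 0.48), the kinase tlk2 (0.58 ± 0.14) and the hyaluronan-binding protease habp2 (0.80 ± 0.20). A fit of the control arrays alone called 1 probe at 24 °C, and the authors' table gave 2 at 32 °C.

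The sex marker genes were read on every array. dmy, the male-determining gene of the medaka Y chromosome and a copy of dmrt1, was above background on 11 of 16 arrays with its probe AB071534, 5 labelled female and 6 labelled male. Its log2 signal was -4.33 ± 1.78 in control females, -4.08 ± 1.62 in control males, -3.48 ± 1.92 in heated females and -3.79 ± 1.54 in heated males (SD, n = 4 each). The male minus female difference of -0.03 did not pass a 2-sided exact permutation test of the sex labels within each temperature (p = 0.978). The probe AY448018 was above background on 9 arrays, 5 labelled female and 4 labelled male, with a male minus female difference of 0.27 (exact p = 0.731). The other dmy and dmrt1 probes named by symbol and the fshr probes were above background on 0 arrays. Because these probes do not separate the labels, the words female and male stand for the labels of the embryos. Both dmy probes above background have names that begin with GT_Xhyb, while those of gsdf and foxl2 begin with GT_Spec. If the first prefix marks cross-hybridising probes, as it reads, the dmy signal cannot test the labels.

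gsdf, a growth factor of the male gonad pathway, was above background in 5 embryos labelled female and 8 labelled male. Its signal was 1.44 higher in embryos labelled male (exact permutation p = 0.0314, adjusted p = 0.157 over the 5 marker probes tested). The heat difference of gsdf was 1.31 ± 0.54 (adjusted p = 0.0861). amh, the anti-Müllerian hormone gene, differed by -0.08 between the sexes (exact p = 0.884) and by 0.72 ± 0.57 with heat (adjusted p = 0.365). foxl2, a factor of the ovarian pathway, was above background on all 16 arrays and differed by -0.14 between the sexes (exact p = 0.236). It rose by 0.34 ± 0.11 with heat over both sexes (adjusted p = 0.0312). No probe for the aromatase gene cyp19a1a was found among the named probes.

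**Figure D5:**
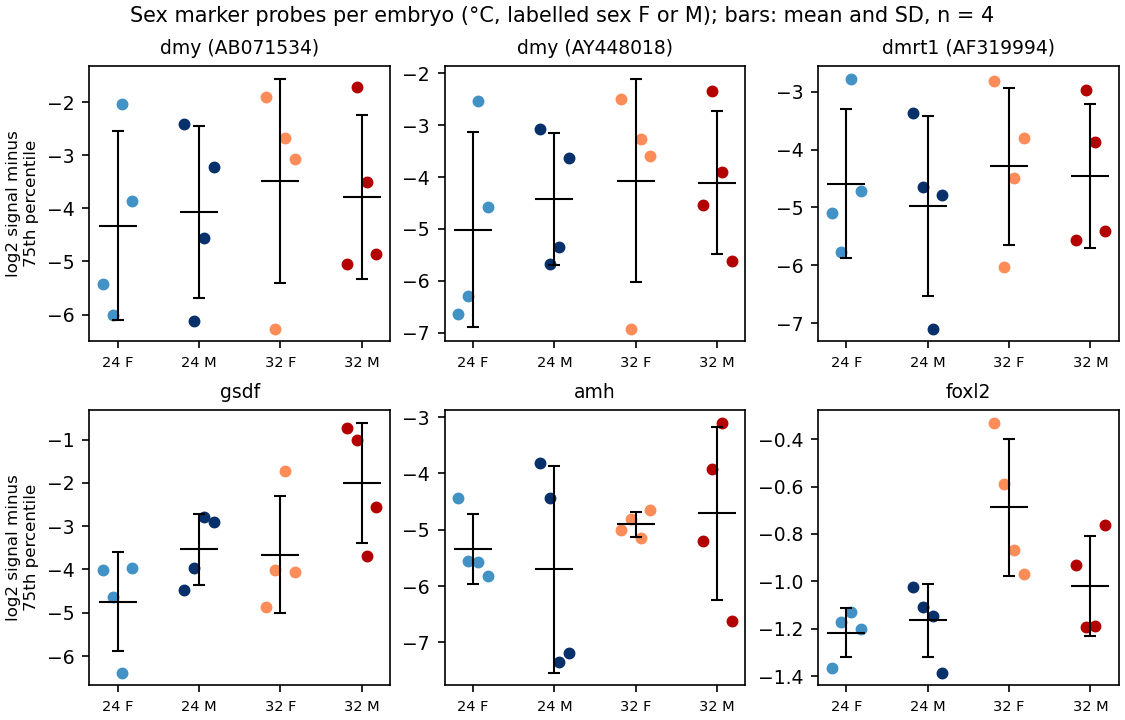
Log2 signal relative to the array's 75th percentile (vertical axis) of 6 sex marker probes in the 4 groups, with 1 point per embryo and bars for the mean and SD (n = 4 per group). The dmy signals of embryos labelled female and male overlap at both temperatures.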

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

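Slide as a block was a planned setting, while scan day as a block was chosen only after the results were seen. Using these blocks, the estimated correlation and reassigned sex labels to weigh explanations for the lists below was also decided only then. The comparison of the responses between the sexes and the check for single embryos far from their group were planned.

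In 7 of 136 groups of 4 embryos checked, 1 embryo lay far from the other 3, and chance gives about 1 in 20 groups, or 6.8. On the second principal component control female 3 lay at -50.86 and the other control females between 10.85 and 18.75 (gap over range 0.8865). The hatching enzyme hce was at -0.06 in control female 4 and between 5.51 and 6.66 in the other 3 (0.8295), and at -1.22 in heated female 4 and between -2.95 and -2.76 in the others (0.8885). The deiodinase dio2 was at -6.78 in control male 2 and between -7.10 and -7.06 in the others (0.8829), where it was not well above background. The transporter slc38a11 was at -5.0 in heated male 3, against -4.58 to -4.52 (0.8792). The syntaxin stx12 was at -6.90 in heated female 1, against -3.19 to -3.0 (0.9516), and at -7.24 in heated male 2, against -3.66 to -3.03 (0.8488).

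Gene lists differed between the responses of the sexes in 3 cases: liver (adjusted p = 2.73e-09), ribosomal proteins (3.16e-06) and photoreceptors and retina (0.0268). With an estimated correlation none of the 3 was called (adjusted p = 0.182, 0.803 and 0.803). The photoreceptor call ended with normexp, with slide or scan day as a block and without slide 3 (adjusted p up to 0.681), was kept under 5 other settings, and ended without any 1 of 10 arrays (adjusted p up to 0.220).

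The liver and ribosomal protein lists ranked higher in the response of embryos labelled male than in that of embryos labelled female, with 0 of 18 liver members past the test singly. With slide as a fixed block the camera adjusted p was 1.84e-06 for liver and 0.00172 for ribosomal proteins, and with scan day as a block 2.14e-06 and 0.00244. These p use the preset correlation, under which 95 of 100 reassignments of the sex labels gave at least 3 called lists. They therefore cannot decide whether slides or scan days play a part. Members that vary together between embryos may account for both calls, since the adjusted p was 0.182 and 0.803 with an estimated correlation. When sex labels were reassigned within each temperature, 1 of 100 assignments, the real one, gave as small a p for liver (6.83e-11, smallest other 9.51e-11), and 16 of 100 did for ribosomal proteins (1.58e-07, smallest other 2.08e-23). Liver was picked for the smallest p of 40 lists, and in 37 of the 100 assignments some list had a p as small (smallest other 6.39e-32), so chance is not excluded for either list. As 95 of the 100 assignments gave at least 3 called lists, a sex difference in the liver response stays a hypothesis.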

How the results depend on the processing

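Scan day as a block, leaving out slide 3, temperature alone and normexp with quantile normalization were tests chosen only after the results were seen, and the others were planned. Causes were not tested, except where a setting's construction shows one: a 2-fold minimum leaves fewer calls. Signal over background limits the folds of genes dim in 1 group to lower bounds.

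The female count of 1257 became 14 with normexp and 75th percentile scaling (12 higher and 2 lower), 308 with slide as a fixed block, 169 with the female arrays alone, 417 with a 2-fold minimum and 373 without slide 3, and ranged from 422 without control female 2 to 2263 without control female 4. The male count of 1868 became 107 (90 higher and 17 lower), 487 and 754 under the first, second and 2-fold settings, 4593 with array weights and 682 with scan day as a block, and ranged from 663 without control male 1 to 2342 without heated female 1. Over both sexes 5045 became 408 with normexp and 829 with the 2-fold minimum, and ranged from 3926 without control male 1 to 5464 without control female 4. The 759 probes called alike in both sexes became 12 with normexp, 132 with slide as a fixed block, 275 with scan day and 286 without slide 3, and ranged from 334 to 1138. Normexp with quantile normalization in place of the 75th percentile gave 1352, 1844, 4732 and 820. The cause of the low normexp counts was not tested.

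Other settings kept the 4 counts within 1.5 times where they were run, and the count called alike was not run with the other filters, the trend, array weights, the compared groups alone or the 2-fold minimum. Quantile normalization gave 1431, 1874 and 5058 in females, males and both, and median scaling 1141, 1573 and 4506. Slide as a random block gave 1359, 1925 and 5155 (correlation within slides 0.0323). The next settings tested other sets of probes. No filter (22773 probes) gave 1104, 1586 and 4916. The 14629 probes above background on all 16 arrays gave 1158, 1708 and 4259, where the main fit called 996, 1507 and 4094 of them. The authors' values gave 1020, 1521 and 3406 over 11651 probes, where the main fit called 831, 1299 and 3313 of them. Temperature without sex labels gave 5428 calls.

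Male against female counts were 0 apart from 1 at 24 °C with the control arrays alone, 2 at 32 °C in the authors' table, and ranges of 0 to 1 and 0 to 2 over single arrays left out. The difference of the responses had 0 calls under each setting. Called gene lists numbered 10 to 12 without 1 array. Of 360 list results over both sexes under the other settings, 349 kept their side of the threshold, 4 lost and 7 gained a call. The sex markers gave 0 adjusted calls under the 4 settings run for them, with 2 of the 5 probes in the authors' table.

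Of 3390 values of named genes under settings other than leaving out an array, 3039 kept direction and side, 296 lost and 54 gained a call, and 1 reversed: pfdn6 in females, 0.22 under normexp. Of 3776 with 1 array left out, 3472 kept both, 266 lost and 38 gained a call and 0 reversed.

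The replicate numbers gave no sign of pairing control with heated embryos, though only 4 pairs per sex could be read. Deviations of same-numbered control and heated embryos had median correlations of -0.0354 in females and -0.0124 in males, and 0% of pairs were over 0.1. Between all groups 16.7% of same-numbered and 19.4% of other pairs were over 0.1. The highest correlation, 0.381, was between control female 4 and control male 4. With the replicate block the counts were 1094, 1610, 4805 and 672, and 11 lists were called.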

Other observations

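The tests on hatching enzymes, on the male-determining gene and on reassigned temperature labels, and the choice of the genes without a symbol, were made only after the results were seen, while the members of fixed lists follow the naming rule.

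Among transcripts without a symbol, named here after their values were seen, an ammonium transporter (Rh type B-A-like, XM_004069140) was at least 49.3-fold higher at 32 °C over both sexes (fitted log2 difference 6.38 ± 0.37). A pair of hepcidin-like transcripts, of the iron-regulating and antimicrobial hormone family, rose by 6.33 ± 0.88 (XM_004085408) and 5.89 ± 0.81 (XM_004085410). The antimicrobial LEAP-2-like XM_004074820 rose by 3.14 ± 0.46 and complement C1q A-like XM_004085698 by 3.36 ± 0.50. Mitochondrial uncoupling protein 2-like XM_004085951 rose by 3.90 ± 0.40, liver-type fatty acid-binding protein-like XM_004072210 by 3.49 ± 0.80, arginase-1-like XM_004080701 by 2.96 ± 0.45 and HSP 90-alpha-like XM_004083771 by 2.69 ± 0.17. The neuropeptide cart ch4 (AB568293) rose by 3.12 ± 0.29. Muscle genes went both ways: a myosin heavy chain (XM_004085570) was at least 4.32-fold higher, while a fast skeletal myosin (XM_004071359) and fast troponin I (XM_004069372) fell (-3.03 ± 0.18 and -2.11 ± 0.37). ID-4-like XM_004077612, an inhibitor of differentiation factors, fell by 2.19 ± 0.17.

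Members of lists that were not called also changed over both sexes. In the thyroid axis, thyroglobulin tg rose by 1.79 ± 0.37 and dio3, which inactivates thyroid hormone, fell by 0.85 ± 0.14, beside the rise of dio2. The growth hormone feedback gene socs2 rose by 1.52 ± 0.14, tyrosine aminotransferase tat by 1.80 ± 0.38 and the renal sulfate transporter slc13a1 by 2.11 ± 0.32. Of 14 glycolysis and gluconeogenesis genes 4 fell, among them tpi1 (-0.64 ± 0.12) and eno1 (-0.44 ± 0.09). Of 50 ribosomal protein genes 9 rose and 1 fell, with rps10 at 1.30 ± 0.09. The germ cell genes tdrd7 and tdrd5 rose by 1.1 ± 0.24 and 1.06 ± 0.30. Genes of the ovarian pathway went both ways, with wnt4b (-1.18 ± 0.29) and esr2 (-0.65 ± 0.20) lower and foxl2 (0.34 ± 0.11) higher. The RNA came from whole embryos, so these values do not show a change in the ovary. The esr2 call ended without any 1 of 5 arrays (adjusted p up to 0.0584), and that of cirbp, given next, without control male 1 or heated male 2 (0.0510). The cold-inducible cirbp (-0.86 ± 0.26), the DNA methyltransferase dnmt3a (-0.75 ± 0.17) and the melatonin enzyme aanat2 (-0.90 ± 0.20) fell as well. The steroid carrier star rose by 0.78 ± 0.20, xanthine dehydrogenase xdh by 1.14 ± 0.19 and the muscle light chain mylpf by 1.37 ± 0.23.

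The hatching enzymes were far lower in heated embryos. Slides and dim arrays argue against themselves as the cause, since the smallest fall within a slide was -4.58 on the log2 scale and heated arrays had 0.982 percentage points more probes above background. A candidate explanation is that heated embryos were further along in development when collected. For each of the 8 control embryos, the hatching enzyme signal was taken minus the mean of the other control embryos of its labelled sex. A lower value went with a score nearer to the heated embryos over the other called probes, taken against the same embryos. The Pearson r was -0.889 (permutation p = 0.00208) and the Spearman rho -0.762 (permutation p = 0.0368, 1 relation computed). Without control female 4 and control male 4, the 2 farthest from the median, r was -0.598 (permutation p = 0.210). The relation thus rests on these embryos, and development stays open. Values within a labelled sex are tied to each other by construction, while the permutations ran across the sexes, so these p are approximate. A direct effect of temperature on these genes, which the design also allows, was not tested. Position on the slide, which went with temperature within each slide, was not tested either.

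The signal of the dmy probes did not follow the sex labels. Names of both dmy probes above background, and of the dmrt1 probe used below, begin with GT_Xhyb. If that prefix marks cross-hybridising probes, as it reads, their signal cannot show whether a label is wrong. Over the 16 arrays the dmy probe AB071534 rose with a dmrt1 probe, AF319994 (Pearson r = 0.798, permutation p = 3e-04, adjusted p = 4e-04 over 4 relations, Spearman rho = 0.826, permutation p = 1.7e-04), with r = 0.841 without the 2 farthest arrays and 0.696 within slides, which is consistent with a probe that also reads dmrt1. A mislabelled embryo cannot be told apart from this with these data, since gsdf, which was 1.44 higher in embryos labelled male (exact p = 0.0314, adjusted p = 0.157) and above background in 8 of 8 of them and 5 of 8 labelled female, but overlaps between the labels, gave r = -0.0363 with dmy (permutation p = 0.894, rho = -0.0706). Slides held 48.9% of the variance of the dmy signal (permutation p = 0.185 with 100000 reassignments) and stay open too. No biological explanation was tested.

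Other splits of the same arrays show how often relabelled arrays gave counts as large. Of the 35 splits of the 8 arrays labelled female, 1, the real one, gave 1257 probes, and the highest other split gave 127. For males 1 of 35 did, with 1868 against a highest other count of 0. Of 100 assignments of temperature within each sex, 1 gave 5045 probes over both sexes (highest other 2604, in an assignment that kept the temperature of 14 of the 16 arrays) and 1 gave 759 probes called alike in both sexes (highest other 0). No other split or assignment that was run reached these 4 counts. This makes chance an unlikely source of them, but 35 splits or 100 assignments cannot exclude it. For the number of called gene lists chance stays open, since 30 of 100 assignments gave 11 or more (highest other 16). For the counts of 0 the splits decide nothing, since no split can give fewer: 35 of 35 between the sexes at 24 °C gave as many (highest other 2), as did 35 of 35 at 32 °C (highest other 16) and 100 of 100 for the difference of the responses (highest other 56).

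Of the called lists taken singly, 2 of 100 assignments gave as small a camera p for cholesterol synthesis and 4 for leukocytes, 6 for antioxidant genes, 7 for inflammation and interferon and 9 for fatty acid oxidation. The number was 13 for neurons, 16 for chaperones, 19 each for liver and for cartilage and bone, 23 for exocrine pancreas and intestine and 27 for cell cycle.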
